A study of Solanum lycopersicum x Solanum pennellii and Solanum lycopersicum with 21 samples.

How the data were processed

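Anthers of the domesticated tomato M82 and of 4 introgression lines were measured on 21 Affymetrix arrays, 6 of M82, 3 of IL-1_1_3 and 4 each of IL-4_2, IL-7_2 and IL-8_1_1. The deposited table holds one log2 expression value per probe set and array, and the log2 scale was read from the range of the values. The affy package made these values, per the submitters' processing notes, and its version and the summarisation and normalisation methods are not given in the sources used here. Near-equal medians of the arrays (9.49 to 9.55) show that the arrays had been scaled to each other before deposit. RNA was extracted with Trizol and column purification and labelled with biotin, per the labels' protocols. No scan date or batch is given in the labels, so no batch was tested. Samples were grouped by their titles, and for IL-1_1_3 and IL-8_1_1 the line characteristic gives the shorter names IL-1_1 and IL-8_1. Titles of the 6 M82 arrays read Pollen Control M82, while titles of the lines name no tissue.

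The table had 10209 probe sets and no missing values. The 108 control probe sets with the prefix AFFX were left out and 10101 were tested. A further 63 reporter probe sets (prefix RPTR) were kept; counts with and without them had both been seen, and the version fixed before the data were examined was used. The platform's annotation table, which can be old, gave 1 gene symbol to 909 probe sets (802 genes), several symbols to 0 and none to 9192, so that 9.00% of the probe sets tested had a name. Of these, 702 probe sets (626 genes) had an informative symbol. Probe sets without a symbol are unnamed here, which does not mean that they lack a gene. Symbols were kept as the table gives them.

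Each line was compared with M82, and each line with each other line, in 1 linear model of the 5 groups over all 21 arrays with 16 residual degrees of freedom (limma 3.58.1 in R 4.3.3, lmFit and eBayes, data.table version 1.17.8). P-values were adjusted within each comparison by the Benjamini-Hochberg method, and a probe set was called at an adjusted p of 0.05. Where a gene had several probe sets, the one with the highest mean over all arrays stood for it and disagreement is stated. Errors beside levels are SD over arrays, and errors beside log2 changes are standard errors of the model. Genes were named by a rule fixed before the data were examined. It took the 8 largest rises and 8 largest falls among called genes with an informative symbol, and the up to 3 called members of each fixed list with the smallest adjusted p. For all 4 lines together it took up to 10 genes with an informative symbol called in the same direction. No such gene was found there, so the 4 unnamed probe sets called in all 4 lines are given by ID. Where fewer than 8 genes were called in a direction, up to 2 unnamed probe sets with the largest change were added. For a list with no called member, the member with the smallest p is given within a range and not by name.

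Gene lists were written as patterns of gene names before the data were examined: pollen, pectin enzymes, cell wall structure and loosening, sugar and starch, photosynthesis, ribosomal proteins, heat shock, ubiquitin, defence, jasmonate, ethylene, auxin, gibberellin, abscisic acid and desiccation, phenylpropanoids, histones and cell cycle, cytoskeleton and signalling, MADS box, redox, surface lipids, respiration, and tapetum. The annotation table held short symbols, of which the patterns matched 12. The symbols were therefore assigned to these lists by hand, after counts of calls, the loadings of the within-group axis and the control probe sets had been seen and before the change of any named gene had. This placed 273 genes in 21 lists, and the tapetum list had no member. Membership does not follow the patterns in each case. MAN2 and TLRP (cell wall), POR2 (photosynthesis), HPL (jasmonate) and DHAR2 (redox) were placed although their names as given here match no term of the pattern. Xegip was left out of the cell wall list although its name does match. The 19 lists with at least 5 measured genes were tested with camera at its preset correlation of 0.01 among 9994 genes and unnamed probe sets, and again with a correlation estimated per list. Lists of fewer genes (surface lipids and respiration) were not tested.

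The within-group axis is the first principal component of the deviations of each probe set from its group mean, which held 59.2% of the within-group variance. Correlations across arrays used deviations from group means and permutation tests. Correlations of changes that share the M82 arrays were set beside 100 simulated sets of unchanged groups made by permuting the residuals across arrays. Up to 100 other splits of the same arrays were refitted for each count. The model was tested on simulated data with independent noise for 10101 probe sets, where it recovered, at log2 changes of 0.5, 1 and 2, 50.7%, 80.6% and 100% in IL-1_1_3, 55.2%, 80.6% and 95.5% in IL-4_2, 58.2%, 88.1% and 95.5% in IL-7_2, and 53.7%, 88.1% and 95.5% in IL-8_1_1. Of the calls in those simulations, 8.28%, 3.12%, 3.55% and 4.79% were unchanged probe sets.

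The alternatives were a fit of only the groups compared, the replicate number as a block, median centring, quantile and cyclic loess normalisation, leaving out the dimmest 0.25 of probe sets, an intensity trend with a robust prior, array weights, an adjusted p of 0.01, a change of at least 1 on the log2 scale, adjustment over the 4 comparisons together, an unmoderated two-sample test, and each array left out in turn. For lists they were the estimated correlation, all probe sets, the dimmest 0.25 left out, the block and each array left out. Chosen after seeing the data were leaving out the 3 arrays that stood apart from their groups, the axis score as a covariate, and leaving out the RPTR probe sets. A test of calls by chromosome was planned and not run, because no table of chromosome positions was used here. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.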

Results

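Transcript levels were measured in anthers collected 1 day before flowers opened, on 21 Affymetrix tomato arrays. The samples were 6 arrays of M82, the domesticated parent, and arrays of 4 introgression lines, which carry a segment of the wild relative Solanum pennellii. The series design calls the lines hybrids, and the labels do not say whether a line carried 1 or 2 copies of its segment, so a fall against M82 has no fixed meaning per copy. IL-1_1_3 had 3 arrays, and IL-4_2, IL-7_2 and IL-8_1_1 had 4 arrays each. The log2 values ran from 3.39 to 14.69, and the median of an array lay between 9.49 and 9.55. Array values carry no read depth, so the number of arrays limited the precision. Signal over background is not given, so changes of dim probe sets are differences of measured values and may understate the change in transcript. Arrays of the same group correlated at 0.925 to 0.998 across probe sets, which are not independent replicates. The first principal axis of the deviations from group means held 59.2% of the within-group variance. Its mean score was -12.0 ± 24.0 (SD, n = 6) in M82, 18.2 ± 11.6 (n = 3) in IL-1_1_3, 6.42 ± 14.4 (n = 4) in IL-4_2, -7.29 ± 47.0 (n = 4) in IL-7_2 and 5.27 ± 16.2 (n = 4) in IL-8_1_1. Exact two-sided permutation tests of these scores against M82 gave p = 0.0714, 0.21, 0.867 and 0.257 for the 4 lines in that order, and 0.286, 0.343, 0.867 and 0.343 after Benjamini-Hochberg adjustment. The labels do not say whether replicates came from separate plants, so the p-values measure the spread between these samples, which may be technical.

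**Figure D1:**
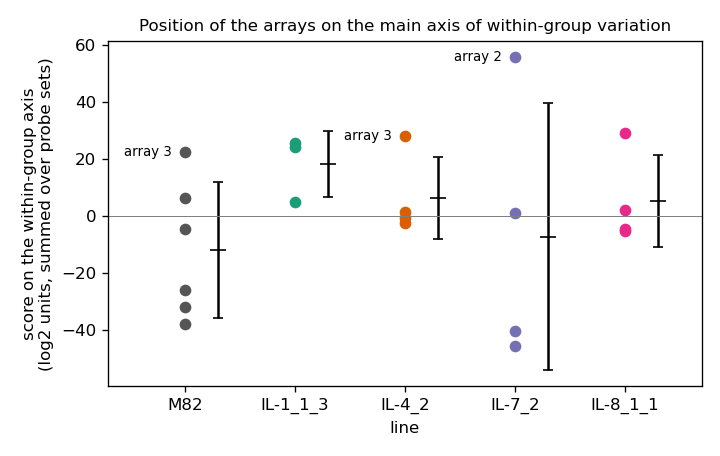
Scores of the 21 arrays (y axis, summed log2 units) on the main axis of within-group variation, by line (x axis), with mean and SD as black bars. Scores of IL-7_2 ran from -45.7 to 55.9 and those of M82 from -38.0 to 22.5.

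The first comparison asked how anthers of IL-1_1_3 differed from those of M82. The largest fall of a gene with an informative symbol was in XTH16 (Les.4008.1.S1_a_at), a xyloglucan endotransglucosylase that remodels cell walls, from 11.42 ± 1.14 (SD, n = 6) in M82 to 8.52 ± 0.82 (n = 3). Its log2 change was -2.90 ± 0.60 (SE, adjusted p = 0.0222), and its other 2 probe sets also fell (-2.80 and -2.90). SDH (Les.5684.1.S1_at) fell 2.54-fold, from 12.04 ± 0.09 to 10.70 ± 0.03 (log2 change -1.34 ± 0.08, adjusted p = 1.86e-09), and all 3 arrays lay below every M82 array. Smaller falls were found in POR2, a protochlorophyllide oxidoreductase (-0.83), CRTL-E-1, a lycopene epsilon-cyclase (-0.83), CAB6A, a chlorophyll a/b binding protein (-0.73), and SODCP.2, a chloroplast superoxide dismutase (-0.52). EIL2, a transcription factor of ethylene signalling, fell by 0.86 on the log2 scale. The transcription factor genes WRKYIId-4 (0.97) and DREB3 (0.56) rose, as did NPR1, a regulator of the salicylic acid response (0.41), and BL3 (0.31).

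Of the 9 measured photosynthesis genes, 2 fell in IL-1_1_3 (CAB6A and POR2) and 7 did not pass the test, although all 9 had a log2 change below 0 (median -0.73). Array 2 carried much of this: the list's mean was -1.10 there and -0.45 and -0.23 in arrays 1 and 3, beside -0.32 to 0.22 in the M82 arrays, and without array 2 the mean change went from -0.59 to -0.34, with 8 of 9 genes below 0 (camera, adjusted p = 0.00721). Adjusted over the list alone, 6 fell. The list passed a set test against all other genes (camera, adjusted p = 5.15e-05), which was lost with adjusted p = 0.641 with an estimated correlation. These 3 arrays also had the highest mean score on the within-group axis, 18.2 against -12.0 in M82, while that axis and the list's mean correlated at r = -0.038 across the 21 arrays within groups (permutation p = 0.867, also after adjustment over 5 relations; Spearman's rho = -0.0506, permutation p = 0.841; r = -0.148 without IL-7_2 array 2 and M82 array 3). The list of 44 cell wall genes held 1 fall (XTH16), that of 46 ethylene genes 1 (EIL2) and that of 20 redox genes 1 (SODCP.2). In the 17 lists with no called member, the member with the smallest p had a log2 change between -1.20 and 1.03 and an adjusted p of 0.0619 or more.

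In the test of all 10101 probe sets with limma, 95 rose and 104 fell in IL-1_1_3, and 2033 had an unadjusted p under 0.05, where 505 were expected by chance. After cyclic loess scaling the split was 58 rises and 115 falls, and in the fit of IL-1_1_3 and M82 alone 49 and 37. Changes of at least 2-fold were 10 rises and 44 falls (81.5% falls). Of the unnamed probe sets, Les.840.1.A1_at rose most (log2 change 5.90, from 4.70 ± 0.30 to 10.60 ± 1.05, adjusted p = 2.52e-10), ahead of Les.2164.1.A1_at (log2 change 1.62). The largest falls of unnamed probe sets were in LesAffx.67882.1.S1_at (log2 change -5.02, to 5.30, adjusted p = 1.38e-12) and Les.2320.1.A1_at (-4.34, to 5.35). The count of 199 calls moved to 587 without M82 array 3 and to 126, 95, 84 and 61 without M82 arrays 1, 2, 5 and 6, and to 88, 43 and 64 without IL-1_1_3 arrays 1, 2 and 3. Calls of 12 of the 19 named results ended when 1 array was left out, among them XTH16 (adjusted p = 0.147, 0.088 and 0.0558 without IL-1_1_3 array 2, IL-1_1_3 array 3 and M82 array 6), CAB6A (0.183 without IL-1_1_3 array 2 and 0.057 without M82 array 6) and Les.2164.1.A1_at (0.13 without IL-1_1_3 array 2). EIL2 ended without each IL-1_1_3 array in turn (0.0861, 0.165 and 0.0873), and POR2, CRTL-E-1, SODCP.2, WRKYIId-4, DREB3, NPR1 and BL3 ended without at least 5 arrays in turn (adjusted p up to 0.236). Of the genes with symbols SDH alone kept its call, as did the other 3 unnamed probe sets with large changes.

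The second comparison asked the same of IL-4_2. CS2 (Les.3660.1.S1_at), a chorismate synthase, rose 2.39-fold, from 9.71 ± 0.19 (SD, n = 6) in M82 to 10.97 ± 0.10 (n = 4), with all 4 arrays above every M82 array (log2 change 1.26 ± 0.12, adjusted p = 1.59e-06). SK, a shikimate kinase of the same pathway, fell (-0.81, adjusted p = 0.000445). MT3 (Les.3579.1.S1_at) had the largest rise of a gene with an informative symbol, from 7.43 ± 1.17 to 10.45 ± 0.99 (log2 change 3.02 ± 0.64, adjusted p = 0.0142), with 3 of 4 arrays above every M82 array. TLRP, a tyrosine- and lysine-rich cell wall protein (-1.26), LePIP1 (-1.11) and IAA16, an Aux/IAA protein of auxin signalling (-1.05), fell, as did NITF (-0.76), ide (-0.39) and ADC, an arginine decarboxylase (-0.31). A second probe set of IAA16 had a log2 change of -0.72 and did not pass (adjusted p = 0.14).

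No gene list passed the set test in IL-4_2 (lowest adjusted p = 0.0568 with camera, 6 lists at an unadjusted p under 0.05, and 0 lists past the threshold with an estimated correlation), but this depended on the arrays and settings: 5, 2 and 4 lists passed without M82 arrays 2, 3 and 5, and 3 without IL-4_2 array 4 (photosynthesis among them, adjusted p = 0.0446), with the dimmest 0.25 of probe sets left out or with the replicate number as a block. The photosynthesis list had a median log2 change of -0.24, with 8 of 9 members below 0 and none called. The cell wall list held 1 fall (TLRP) among 44 genes and the auxin list 1 (IAA16) among 9. For the 19 lists with no called member, the member with the smallest p had a log2 change between -1.25 and 0.63.

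Over all probe sets, 89 rose and 96 fell in IL-4_2, and 1263 had an unadjusted p under 0.05. After cyclic loess scaling the split was 66 rises and 101 falls, and with the axis score as a covariate, chosen after seeing the data, 217 and 139. Changes of at least 2-fold were 11 rises and 50 falls. Among unnamed probe sets, LesAffx.62131.1.S1_at (log2 change 3.30) and LesAffx.51554.1.S1_at (2.89) rose most. Les.2423.1.A1_at fell from 12.02 ± 0.21 to 5.51 ± 0.19 (log2 change -6.51, adjusted p = 2.37e-13), and Les.612.1.S1_at fell to 5.93 (-4.80). The 185 calls became 118 without IL-4_2 array 3. Leaving out 1 array ended the calls of MT3 (adjusted p = 0.0716 and 0.0775 without IL-4_2 arrays 1 and 3), LePIP1 (without any 1 of 8 arrays, up to 0.201) and TLRP (without any 1 of 8, up to 0.135), and the other named genes kept theirs.

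The third comparison, of IL-7_2, found its largest fall of a gene with an informative symbol in FLACCA. FLACCA (Les.3454.1.S1_at), the molybdenum cofactor sulfurase needed for the last step of abscisic acid synthesis, fell from 10.26 ± 0.13 (SD, n = 6) in M82 to 6.21 ± 0.29 (n = 4; log2 change -4.05 ± 0.11, adjusted p = 2.7e-14). HPL (Les.3478.1.S1_at), a hydroperoxide lyase that cleaves fatty acid hydroperoxides, fell 3.70-fold, from 13.65 ± 0.04 to 11.76 ± 0.58 (adjusted p = 2.37e-07). DGK1 (Les.3526.1.S1_a_at), a diacylglycerol kinase, fell from 8.75 ± 0.35 to 6.47 ± 0.75 (log2 change -2.29, adjusted p = 8.13e-06). All 4 arrays of IL-7_2 lay below every M82 array for these 3 genes. Further falls were in Xegip, a xyloglucan endoglucanase inhibitor (-2.18), ctu1 (-1.62), 20ox-2, a gibberellin 20-oxidase (-1.58), ARPI (-1.32) and DIG3 (-0.71).

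Among the gene lists in IL-7_2, single genes changed. Of 9 pectin enzyme genes, 2 rose, the pectin methylesterase genes PME2.1 (2.02 ± 0.38, adjusted p = 0.00434) and PE1 (0.33 ± 0.05, adjusted p = 0.00104), and of 44 cell wall genes, 2 rose, the xyloglucan endotransglucosylase gene tXET-B2 (2.14 ± 0.47, adjusted p = 0.014) and the endo-mannanase gene MAN2 (1.51 ± 0.35, adjusted p = 0.0206). Neither list passed as a set (adjusted p = 0.971 and 0.677). Xegip, which fell, had been left out of the cell wall list by hand although its name matches that list's pattern. MKK3, a MAP kinase kinase (0.63), and HT3, a hexose transporter (0.39), rose too. The photosynthesis list passed (camera, adjusted p = 7.95e-05; adjusted p = 0.284 with an estimated correlation): 1 of its 9 genes fell (PsbQ of photosystem II, -0.40), 8 did not pass, all 9 were below 0 (median -0.40), and 5 fell adjusted over the list alone. Falls were also found for 1 of 13 defence genes (P69A, a subtilisin-like protease, -0.68) and 1 of 6 cytoskeleton and signalling genes (CDPK1, a calcium-dependent kinase, -0.58). FLACCA was the 1 fall among 6 abscisic acid genes, HPL among 13 jasmonate genes and 20ox-2 among 9 gibberellin genes. In the 12 lists with no called member, the log2 change of the member with the smallest p lay between -0.18 and 0.48.

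Across all probe sets, 172 rose and 115 fell in IL-7_2 and 1379 had an unadjusted p under 0.05, with 28 rises and 59 falls among changes of at least 2-fold (67.8% falls). After cyclic loess scaling the direction of the majority turned, with 93 rises and 135 falls, as it did in the fit of IL-7_2 and M82 alone (42 and 64), with the replicate number as a block (60 and 77), at an adjusted p of 0.01 (71 and 82) and in the unmoderated test (49 and 51). Of the unnamed probe sets, Les.868.1.A1_at (log2 change 2.80) and Les.1859.3.S1_at (2.79) rose most. The fit of IL-7_2 and M82 alone called 106 probe sets against 287, and the fit with the axis score as a covariate, chosen after seeing the data, called 961. Calls of 8 of the 23 named results ended when 1 array was left out, namely MAN2 (0.0791 without IL-7_2 array 1 and 0.0598 without array 3), MKK3 (0.0557 and 0.0595 without arrays 2 and 3), ctu1 (0.0725 without array 3), and 20ox-2, ARPI, HT3, P69A and PsbQ (adjusted p up to 0.124, each without at least 3 arrays in turn).

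In IL-8_1_1, HY5 (Les.3543.1.S1_at), a bZIP transcription factor of the light response, fell 5.05-fold, from 9.78 ± 0.15 (SD, n = 6) in M82 to 7.45 ± 0.31 (n = 4), with all 4 arrays below every M82 array (log2 change -2.34 ± 0.12, adjusted p = 1.21e-10), and array 4 stood apart at 7.91. Wiv-1 (Les.3460.1.S1_at), an acid invertase that splits sucrose, rose 3.72-fold, from 7.61 ± 0.37 to 9.50 ± 0.52 (log2 change 1.89 ± 0.25, adjusted p = 0.000104). The transcription factor gene WRKYIId-1 rose (1.49, adjusted p = 0.00762; array 3 stood apart at 9.93), as did cevi19 (1.37), BL2 (0.72) and SSTLE1 (0.58). PMM, a phosphomannomutase, fell (-2.99 ± 0.41, adjusted p = 0.000163), but its probe sets disagreed, with log2 changes of -5.94 (adjusted p = 4.25e-09) and -0.29 (adjusted p = 0.851) for the other 2. PRO2, a gene of proline synthesis, fell by 0.51 on the log2 scale.

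Single members of 4 lists rose in IL-8_1_1: Wiv-1 among 24 sugar and starch genes, DHAR2, a dehydroascorbate reductase, among 20 redox genes (0.75), LOX1.1, a lipoxygenase, among 13 jasmonate genes (0.70), and THT7-8, a tyramine hydroxycinnamoyltransferase, among 9 phenylpropanoid genes (0.48). No list passed the set test (lowest adjusted p = 0.102 with camera, 2 lists at an unadjusted p under 0.05, and 0 lists past the threshold with an estimated correlation), and 1 passed without M82 array 1, without IL-8_1_1 array 1 or with the dimmest 0.25 left out. The photosynthesis list had a median of -0.12 (adjusted p = 0.327). For the 17 lists with no called member, the member with the smallest p had a log2 change between -0.60 and 1.93.

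Over all probe sets, 63 rose and 82 fell in IL-8_1_1, and 689 had an unadjusted p under 0.05. Changes of at least 2-fold were 18 rises and 47 falls (72.3% falls). Of the unnamed probe sets, Les.1484.1.A1_at (log2 change -4.62, adjusted p = 2.86e-15) and Les.5762.1.S1_at (-4.29) fell most, while a probe set of PMM fell further (-5.94). The 145 calls became 229 without M82 array 3, IL-4_2 array 3 and IL-7_2 array 2, an alternative chosen after seeing the data. Leaving out 1 array ended the calls of SSTLE1 (adjusted p = 0.0598 and 0.0532 without IL-8_1_1 arrays 1 and 2) and of DHAR2, PRO2, BL2, LOX1.1 and THT7-8 (up to 0.192, each without at least 4 arrays in turn), and HY5, Wiv-1, WRKYIId-1, cevi19 and PMM kept theirs.

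**Figure D2:**
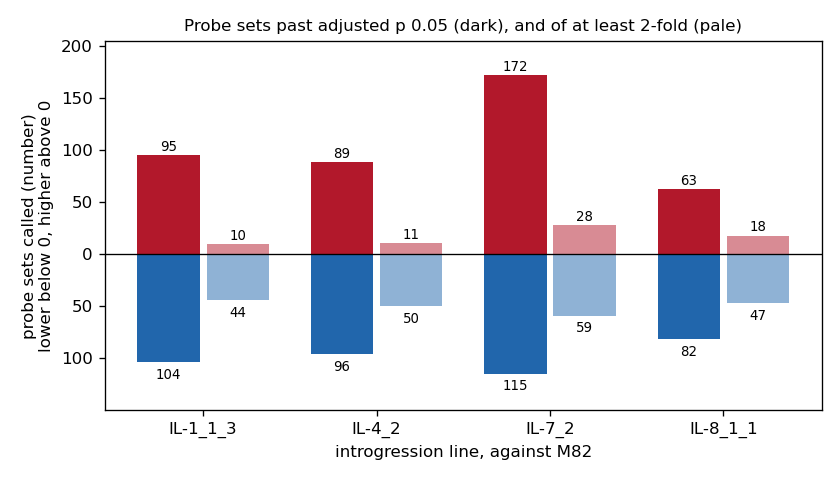
Number of probe sets (y axis) that were higher (above 0) or lower (below 0) than M82 at an adjusted p of 0.05 in each line (x axis), with changes of at least 2-fold as pale bars. Falls outnumbered rises among the changes of at least 2-fold in each line, by 44 to 10, 50 to 11, 59 to 28 and 47 to 18.

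**Figure D3:**
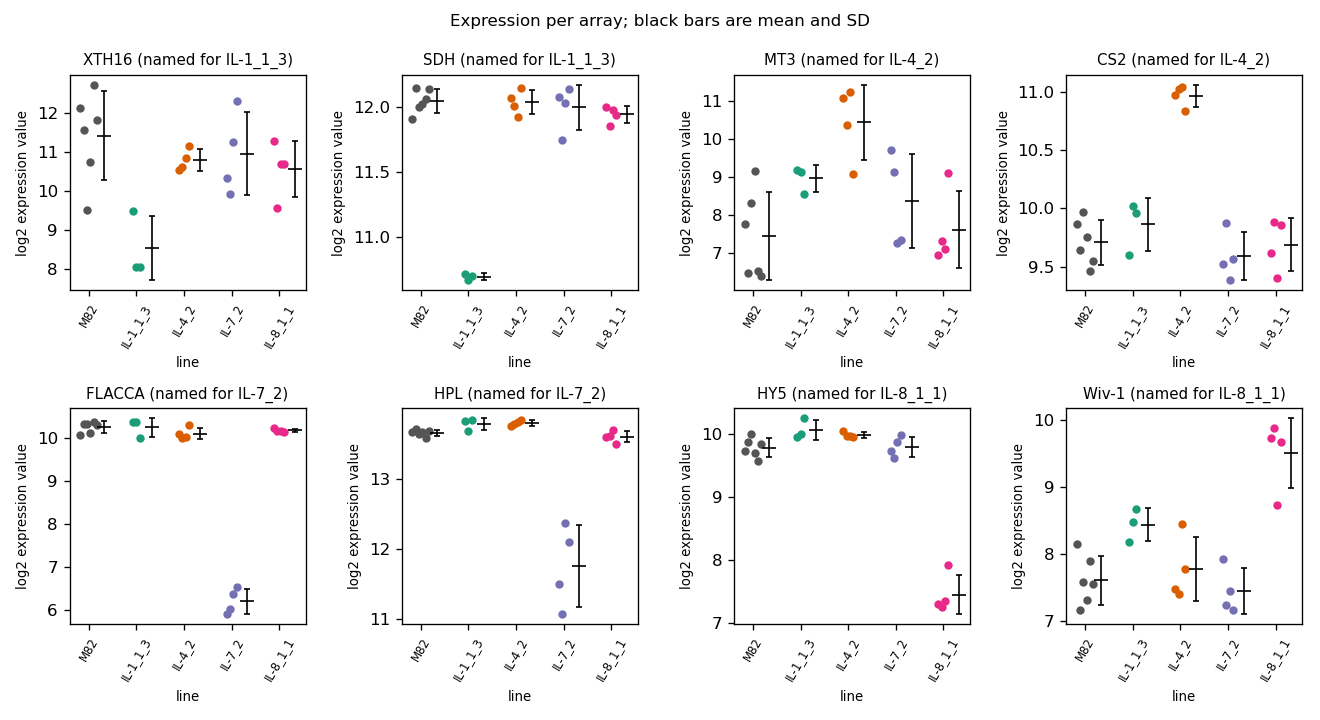
Log2 expression values (y axis) of 8 named genes in each array of the 5 groups (x axis), with mean and SD as black bars. FLACCA lay at 6.21 in IL-7_2 and at 10.26 in M82, and HY5 at 7.45 in IL-8_1_1 and at 9.78 in M82.

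Several of these genes differed between the lines as well as from M82. FLACCA had log2 changes of -0.01, -0.15 and -0.08 in IL-1_1_3, IL-4_2 and IL-8_1_1, and HY5 of 0.29, 0.20 and 0.02 in IL-1_1_3, IL-4_2 and IL-7_2, with adjusted p of 0.224 or more in each of these. Tested between lines, FLACCA was lower in IL-7_2 than in each other line (by 3.90 to 4.05 on the log2 scale, adjusted p = 5.63e-13 or less), and HY5 was lower in IL-8_1_1 than in each other line (adjusted p = 2.21e-10 or less). HPL and DGK1 were also lower in IL-7_2 than in each of the other 3 lines (adjusted p = 3.79e-06 or less), SDH lower in IL-1_1_3 (1.09e-08 or less) and CS2 higher in IL-4_2 (6.85e-05 or less). Wiv-1 was higher in IL-8_1_1 than in 2 of the other lines, and against IL-1_1_3 the difference did not pass (adjusted p = 0.097). XTH16 was lower in IL-1_1_3 than in 1 other line, IL-7_2 (adjusted p = 0.0477), and did not pass against IL-4_2 (0.112) or IL-8_1_1 (0.185). Weaker hybridization of a wild transcript could also lower a gene in 1 line alone. For the genes that were lower, these tests therefore do not tell it from a fall of the transcript.

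Across the 4 lines, 689 probe sets were called in 1 line, 45 in 2, 7 in 3 and 4 in all 4, the last in the same direction. Les.4290.1.S1_at was higher (0.41, 0.46, 0.36 and 0.43 from a mean of 13.10 in M82), and so was LesAffx.50170.1.S1_at (0.83, 0.79, 1.29 and 0.97). LesAffx.124.1.S1_at was lower (log2 changes from -2.25 to -1.37), with IL-4_2 array 3 apart from the other arrays of its line at 6.23, and so was LesAffx.65306.1.S1_at (-0.76, -0.54, -0.43 and -0.57). None of the 4 has a gene symbol here. The 4 became 2 without M82 array 5 or 6, without any 1 array of IL-1_1_3 or IL-4_2, or without IL-8_1_1 array 1 or 3.

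The log2 changes of 2 lines against the shared M82 arrays correlated across probe sets at 0.578 for IL-1_1_3 and IL-4_2, 0.570 for IL-1_1_3 and IL-8_1_1, 0.451 for IL-4_2 and IL-8_1_1, 0.255 for IL-1_1_3 and IL-7_2, 0.125 for IL-4_2 and IL-7_2 and 0.111 for IL-7_2 and IL-8_1_1. The mean of the 6 was 0.348, and unchanged simulated groups gave 0.355. The mean covariance was 0.043 against 0.0196 simulated, a difference of 0.0235 that 12 of 100 draws reached or passed in covariance. With the controls split between the lines the correlations were 0.422, 0.403, 0.261, 0.132, -0.019 and -0.039. IL-1_1_3 and IL-4_2 shared 13 rises and 4 falls, where independent lists of those sizes would share 0.837 and 0.988. IL-1_1_3 and IL-8_1_1 shared 9 rises and 5 falls (0.593 and 0.844 for independent lists). In the same direction and in opposite ones, IL-1_1_3 and IL-7_2 shared 16 and 5 calls (2.80 and 2.85 for independent lists), IL-4_2 and IL-7_2 shared 10 and 4 (2.61 and 2.65), IL-4_2 and IL-8_1_1 shared 9 and 2 (1.33 and 1.32), and IL-7_2 and IL-8_1_1 shared 6 and 4 (2.01 and 2.11). The first 2 pairs had 3 and 0 calls in opposite directions (1.82 and 1.42). Independent lists do not share the M82 arrays, so these numbers do not tell a common effect from the shared controls. Unchanged simulated groups that share the controls had 0 calls in a common direction in every draw for IL-1_1_3 with IL-4_2. The same held for IL-7_2 with each other line. For IL-8_1_1 with IL-1_1_3 and with IL-4_2, 1 of 100 draws reached the observed number. Such groups hold no changes of a line, so they do not show how many calls lists of the observed sizes would share. Beside falls of at least 2-fold, neighbouring probe sets of the same cluster number changed by a median of 63.4% of the fall, and beside rises by 33.8%. The permutation p of 0.869 was one-sided for a smaller share beside falls, so it does not test the larger share seen. Probe sets of a cluster could enter this test more than once.

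Differences between the means of 2 lines did not use the M82 arrays, but those arrays and the other lines entered the error variance of each test. IL-4_2 and IL-7_2 differed in 497 probe sets (216 higher in IL-4_2 and 281 lower), IL-7_2 and IL-8_1_1 in 450 (273 higher in IL-7_2 and 177 lower), and IL-1_1_3 and IL-7_2 in 330 (129 higher in IL-1_1_3 and 201 lower). IL-4_2 and IL-8_1_1 differed in 235 (117 higher in IL-4_2 and 118 lower), IL-1_1_3 and IL-4_2 in 169 (95 higher in IL-1_1_3 and 74 lower), and IL-1_1_3 and IL-8_1_1 in 149 (86 higher in IL-1_1_3 and 63 lower). After cyclic loess scaling the splits were 183 higher and 192 lower for IL-7_2 against IL-8_1_1, and 136 and 132 for IL-1_1_3 against IL-7_2. With only the 2 groups fitted, the first 3 counts were 204, 156 and 75. Without IL-7_2 array 2, they were 1483, 957 and 2131, and the last of these was 183, 177 and 208 without IL-1_1_3 arrays 1 and 2 and IL-7_2 array 3.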

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

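Tests of RNA degradation, of anther stage, of the share of rises and of shared calls with the covariate were chosen only after the result was seen; the other tests in this part were fixed before their results.

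Some arrays stood far from the others of their group, by the gap to the nearest array over the range of the group. This was tested in 129 groups of values and marked 7 (5.43%), and chance marks about 1 in 20. That share pools values of whole arrays with values of single genes, so it is not the rate for whole arrays. IL-1_1_3, with 3 arrays, was too small a group to test, so none of its arrays could be marked. In the median correlation with its own group, M82 array 3 lay at 0.975 (next 0.983), IL-4_2 array 3 at 0.989 (next 0.995) and IL-7_2 array 2 at 0.930 (next 0.975). IL-4_2 array 3 also stood apart on the within-group axis, at 28.0 against 1.21 for the next. In IL-8_1_1, WRKYIId-1 was 9.93 in array 3 (next 10.22) and HY5 was 7.91 in array 4 (next 7.34). LesAffx.124.1.S1_at was 6.23 in IL-4_2 array 3 (next 6.79).

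Control probe sets outside the comparisons also differed, in a search for differences in either direction. The 3 that differed were of 1 transcript, in IL-7_2 against M82. AFFX-Le_GlutTrans_3_at had a log2 change of -4.29 (7.38 ± 0.36, n = 4, against 11.67 ± 0.68, n = 6; adjusted p = 1.49e-09 with limma), AFFX-Le_GlutTrans_5_at one of -3.17 (adjusted p = 6.89e-06) and AFFX-Le_GlutTrans_M_r_at one of -3.05 (adjusted p = 7.9e-07).

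The first pattern is the spread of the arrays of each group along 1 axis, with 59.2% of the within-group variance. The stage of the anthers at harvest stays open: the median slopes of 44 cell wall and 46 ethylene genes lay at percentiles 0.02 and 100 of 10000 random lists matched on expression, but these lists were filled and picked after the slopes of probe sets along the axis had been seen, so this does not count for it. RNA degradation stays open, as the 3' minus 5' difference of control transcripts correlated with the score at r = 0.275 (permutation p = 0.169, adjusted p = 0.423 over 5 relations; Spearman's rho = 0.312, permutation p = 0.163; r = 0.153 without IL-7_2 array 2 and M82 array 3), with a 95% interval from -0.237 to 0.667. The share of green tissue stays open too, at r = -0.038 with an interval from -0.509 to 0.451. The labels give no stage, plant or batch within a line, so no biological explanation that the design names was tested.

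The second pattern is that changes of at least 2-fold against M82 were mostly falls. A further quantile or cyclic loess normalisation did not remove the pattern, as the lowest share of falls in a line was 68.6%. The deposited values had already been scaled by a method not given, which these steps cannot undo. Normalisation before deposit therefore stays open. Sequence differences of wild transcripts were taken to lower signals only, a premise that was not tested. Under it, weaker hybridization would not give the rises, 25.1% of these changes (67 of 267, exact 95% interval 20 to 30.7). That share is the complement of the pattern and decides nothing about the falls. For the falls, weaker hybridization stays open. Neighbouring probe sets of the same cluster number, which shared a symbol in 101 of 103 named pairs, changed by 63.4% of the probe set's own change beside 72 falls and by 33.8% beside 22 rises. The difference was 29.6 points, with a 95% interval from -17.9 to 51.7. The permutation p of 0.869 was one-sided for a smaller share beside falls, the opposite of the direction seen. Probe sets of a cluster entered more than once as each other's neighbours, so interval and p treat dependent entries as independent. Weaker hybridization could also lower neighbours of the same transcript together, so this difference decides nothing. Different transcription from the wild segment, the difference between the lines and M82 that the design names, also stays open and was not tested.

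The third pattern is that changes of the lines against M82 went together, with a mean correlation of 0.348. The shared control arrays could give a mean of that size, since unchanged simulated groups gave 0.355 (from -0.198 to 0.853) and 12 of 100 draws had a mean covariance at or above the observed 0.043. By pair, the correlation was reached by 31 to 77 of the draws and the covariance by 3 to 53, least often for IL-1_1_3 with IL-4_2 (3) and with IL-8_1_1 (5). With the controls split between the lines, no array was shared. The correlations were then 0.422, 0.403 and 0.261 among IL-1_1_3, IL-4_2 and IL-8_1_1, and 0.132, -0.019 and -0.039 for the pairs with IL-7_2. Sharing of arrays is not the source of what remained in the pairs without IL-7_2. No spread was simulated for split controls, so a chance position of the arrays is not excluded. Position on the within-group axis stays open. The mean correlation with the score as a covariate was 0.187, but the mean lay inside the simulated range without the covariate too, so that test decides nothing. Calls shared in direction by a pair rose with the covariate, from between 6 and 17 to between 16 and 39, while the mean covariance fell from 0.043 to 0.0147. The covariate also lengthened the call lists of IL-4_2 (185 to 356), IL-7_2 (287 to 961) and IL-8_1_1 (145 to 191), though not of IL-1_1_3 (199 to 198). Longer lists share more calls, so this rise decides nothing about the axis either. Effects common to the lines stay open, as no test excludes them.

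Other splits of the same arrays were refitted to ask, count by count and unadjusted, whether chance can be excluded as the source. Taken alone, chance is unlikely for the calls of IL-1_1_3 against M82 (199, where 1 of 84 splits gave as many, the real split itself, and the highest other gave 21). The same holds for IL-4_2 (185, 1 of 100, highest other 2) and IL-8_1_1 (145, 1 of 100, highest other 4). It is not excluded over all the counts, nor between plants, since the labels do not say whether replicates were separate plants. For IL-7_2 chance cannot be excluded (287, 5 of 100, highest other 4091). Since some of these splits called several times the real count, they point to a structure of the samples. Between lines, the real split alone of 35 gave as many calls for IL-1_1_3 against IL-4_2 (169, highest other 11) and IL-8_1_1 (149, highest other 25). The same held for IL-4_2 against IL-7_2 (497, highest other 99) and IL-8_1_1 (235, highest other 0), and for IL-7_2 against IL-8_1_1 (450, highest other 1). With 35 splits, 1 of 35 is the lowest share possible. Chance is thus unlikely for each of these alone, but it is not excluded over all the counts. Nor can it be excluded for IL-1_1_3 against IL-7_2 (330, with 3 of 35, highest other 3192), which again points to a structure of the samples. For the 4 calls in all lines, 2 of 100 regroupings of all 21 arrays gave as many, the real one included. The highest other gave 251, which points to a structure of the samples here too. These regroupings mix the lines and so break up each line's own calls. They do not show whether lists of the real sizes would share 4 calls by chance, so chance is not excluded there. For the number of gene lists past the threshold, chance cannot be excluded in IL-1_1_3 (1, with 56 of 84, highest other 7) and IL-7_2 (1, with 78 of 100, highest other 5). For IL-4_2 (100 of 100, highest other 7) and IL-8_1_1 (100 of 100, highest other 6) the real number was 0, which every split reaches, so this decides nothing there.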

How the results depend on the processing

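Leaving out 3 arrays, the axis score as a covariate and leaving out the RPTR probe sets were alternatives chosen only after the result was seen. Across 15 counts, 213 of 320 alternative values lay within 1.5 times the reported count and 107 did not. Counts of calls stayed within 1.5 times under median centring, quantile and cyclic loess normalisation, the trend and robust prior, adjustment over the 4 comparisons together, the dimmest 0.25 of probe sets left out and the RPTR probe sets left out. The direction split did move under cyclic loess: falls were 66.5% against 52.3% in IL-1_1_3, 60.5% against 51.9% in IL-4_2 and 59.2% against 40.1% in IL-7_2, and calls lower in the line named first were 49.3% against 60.9% for IL-1_1_3 and IL-7_2, and 51.2% against 39.3% for IL-7_2 and IL-8_1_1. Over all settings but the 2-fold threshold, falls ran from 43.0% to 75.0% in IL-1_1_3, 34.9% to 68.5% in IL-4_2, 32.2% to 60.4% in IL-7_2 and 47.6% to 61.4% in IL-8_1_1. The scalings left the median change of all probe sets against M82 at 0.04 or less. For the moved counts below the cause was not tested, except that a stricter threshold calls fewer by construction.

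Values are in the order IL-1_1_3, IL-4_2, IL-7_2, IL-8_1_1 against M82 (199, 185, 287 and 145 calls) unless named. A fit of only the groups compared gave 86 in IL-1_1_3, 106 in IL-7_2, 75 for IL-1_1_3 against IL-7_2, 204 for IL-4_2 against IL-7_2 and 156 for IL-7_2 against IL-8_1_1. The unmoderated two-sample test gave 49 in IL-1_1_3, 100 in IL-7_2 and 92 in IL-8_1_1. An adjusted p of 0.01 gave 43 in IL-1_1_3, 109 in IL-4_2, 153 in IL-7_2, 155, 287 and 268 for IL-7_2 with IL-1_1_3, IL-4_2 and IL-8_1_1, and 2 in all 4 lines. A change of at least 2-fold gave 54, 61, 87 and 65, 1 in all 4 lines, and between lines 97, 120 and 82 for IL-1_1_3 with IL-4_2, IL-7_2 and IL-8_1_1, 170 and 111 for IL-4_2 with IL-7_2 and IL-8_1_1, and 156 for IL-7_2 with IL-8_1_1. Array weights gave 2525, 1863, 851 and 311, 11 in all 4 lines, and between lines, in the same order, 650, 4302, 759, 4125, 977 and 3246. The axis score as a covariate gave 356 in IL-4_2 and 961 in IL-7_2, which held all 287 reported calls, and between lines, in the same order, 336, 711, 291, 1344, 391 and 1236; IL-1_1_3 had 198 calls, of which 136 were among the 199. Without M82 array 3, IL-4_2 array 3 and IL-7_2 array 2, IL-1_1_3 had 1917 calls, which held all 199, IL-8_1_1 had 229, and IL-7_2 against IL-1_1_3, IL-4_2 and IL-8_1_1 had 2722, 936 and 1517. With only odd or only even numbered controls, 2 and 7 probe sets were called in all 4 lines.

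Gene lists past the threshold (1, 0, 1 and 0) became 3, 3, 2 and 1 with the dimmest 0.25 left out, 0 in IL-1_1_3 and 0 in IL-7_2 with an estimated correlation, 2 in IL-1_1_3 and 1 in IL-4_2 with all probe sets, and 5, 3 and 2 in the first 3 lines without the 3 arrays.

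Leaving out 1 array at a time gave 43 to 587 calls in IL-1_1_3, 118 to 237 in IL-4_2, 216 to 361 in IL-7_2 and 111 to 151 in IL-8_1_1. Between lines it gave 133 to 167 for IL-1_1_3 with IL-4_2, 177 to 2131 with IL-7_2, 370 to 1483 for IL-4_2 with IL-7_2, 190 to 221 with IL-8_1_1, and 325 to 957 for IL-7_2 with IL-8_1_1, and IL-1_1_3 with IL-8_1_1 stayed within 1.5 times. The lowest of IL-1_1_3 came without IL-1_1_3 array 2 and the highest without M82 array 3; the highest of the 3 comparisons of IL-7_2 with other lines came without IL-7_2 array 2. Calls in all 4 lines ran from 2 to 6, and lists past the threshold from 1 to 3, 0 to 5, 1 to 3 and 0 to 1. The lists moved without M82 arrays 2 and 3 in IL-1_1_3 (2 and 3), without M82 arrays 2, 3 and 5 and IL-4_2 array 4 in IL-4_2 (5, 2, 4 and 3), without IL-7_2 arrays 2 and 3 in IL-7_2 (3 and 3), and without M82 array 1 and IL-8_1_1 array 1 in IL-8_1_1 (1 and 1).

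The replicate numbers do not pair the samples: correlations of deviations between arrays of the same number ran from -0.806 to 0.698, and 1 of 19 arrays correlated best with an array of its own number. With the replicate number as a block the calls were 32, 92, 137 and 83, with 184 for IL-1_1_3 against IL-7_2, 2 in all 4 lines, and 3 lists each in IL-4_2 and IL-7_2; it moved no other count by over 1.5 times.

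Of 76 named results, 0 turned direction under 1864 alternative values, 1503 of which kept the call and 361 did not. Calls of 19 results held in every alternative run, among them FLACCA, HPL, DGK1, HY5, PMM, Wiv-1, CS2 and SDH, and 57 ended in at least 1. The settings that ended most were the unmoderated test (43), the threshold of 2-fold (37), the block (36), the groups compared alone (33) and an adjusted p of 0.01 (32). Cyclic loess ended 4 (DREB3, NPR1, HT3 and LOX1.1), quantile normalisation 5 (DREB3, NPR1, BL3, LOX1.1 and TLRP), the axis covariate 3 (CRTL-E-1, DREB3 and WRKYIId-4), and leaving out the 3 arrays 8. Not run were the planned tests by chromosome and without the genes of a line's own chromosome, as no chromosome table was used here, and other pseudocounts, as the values were already on the log2 scale. Signal over background is not given per array, so dim probe sets were limited only by their mean.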

Other observations

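The placing of the lists on the within-group axis was a test chosen only after the result was seen.

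The pollen list (8 genes such as LAT61 and the receptor kinase PRK genes) had all 8 log2 changes above 0 in IL-1_1_3, IL-4_2 and IL-8_1_1 (medians 0.22, 0.19 and 0.20) and 1 of 8 above 0 in IL-7_2 (median -0.06), with 0 genes called and adjusted p from 0.287 to 0.438 in the set test, camera. Its 8 genes stood at percentile 99.9 of random lists on the within-group axis, with 7 of 8 slopes above 0. Ribosomal protein genes stood at percentile 1.48, heat shock genes at 2.34, auxin genes at 0.805 and cytoskeleton and signalling genes at 98.6, and these 5 lists are beside the cell wall and ethylene lists the ones outside the central 95% among 19.

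Beyond photosynthesis, 0 lists passed the set test in any line. Over the 4 lines, medians and adjusted p ran from -0.16 to 0.05 and from 0.327 to 0.971 for pectin enzymes, from -0.18 to 0.05 and from 0.0568 to 0.677 for cell wall genes, from 0.02 to 0.06 and from 0.587 to 0.901 for sugar and starch, from -0.29 to 0.14 and from 0.159 to 0.971 for ribosomal proteins, from -0.33 to 0.05 and from 0.12 to 0.971 for heat shock, and from -0.05 to 0.11 and from 0.249 to 0.997 for ubiquitin. They ran from -0.26 to 0.22 and from 0.0758 to 0.677 for defence, from -0.06 to 0.21 and from 0.105 to 0.833 for jasmonate, from 0.08 to 0.16 and from 0.102 to 0.354 for ethylene, from -0.21 to 0.08 and from 0.0568 to 0.995 for auxin, from -0.10 to 0.02 and from 0.16 to 0.587 for gibberellin, and from -0.12 to 0.02 and from 0.115 to 0.833 for abscisic acid and desiccation. For phenylpropanoids they ran from -0.02 to 0.05 and from 0.635 to 0.971, for histones and cell cycle from -0.07 to 0.08 and from 0.373 to 0.952, for cytoskeleton and signalling from -0.09 to 0.20 and from 0.105 to 0.697, for MADS box from 0.09 to 0.22 and from 0.0568 to 0.677, and for redox from -0.03 to 0.08 and from 0.285 to 0.677. The lists too small to test had medians from -0.24 to 0.52 (surface lipids, 4 genes) and from -0.24 to 0.95 (respiration, 2 genes). In 19 of the 76 pairs of list and line the median, the mean and the test did not share a sign, and 0 of these passed.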
